A study of Arabidopsis thaliana with 10 samples.

How the data were processed

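The series holds RNA-seq of Arabidopsis shoots from seedlings grown for 10 days on diluted solid Murashige and Skoog medium with sucrose, with 5 WT and 5 OE samples and 1 library each. Samples were placed in groups by their titles. The deposited table gives 1 column of FPKM per sample for 32824 genes, normalized by the authors per kilobase of transcript and to the total of each library, as its name states. Per the submitters' processing notes, the tools included Trimmomatic 0.36, FastQC, kallisto 043.1, sleuth and R 3.5.1, without a role for each; the genome build and annotation are not given in the sources used here. Because kallisto also reports other units, the deposited FPKM values were checked: the column sums varied by a coefficient of variation of 2.45%, whereas the sums of value times transcript length varied by 0.836%, as they would for FPKM and not for TPM. No value was rescaled for the main tests.

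The table holds no fragment counts. Depth was estimated from the smallest steps between the values of weakly expressed genes with a single transcript of at least 800 nt, which gave 1.83e+07 to 2.32e+07 fragments per library for an assumed fragment length of 200 nt. Since a gene needs many fragments for a stable value, 8233 genes at 0 in all libraries and those with a mean under 1 FPKM over the 10 libraries were left out, which kept 17713 genes. No 2 columns were identical.

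Gene identifiers were matched to the RefSeq annotation of the assembly TAIR10.1, from which symbols, products, transcript lengths, GC content and annotation terms were taken, for 32539 of the 32824 identifiers. The other 285 belong to the plastid genome (133) and the mitochondrial genome (152) by their locus codes. No coordinates were used, since the build of the deposited values is not known.

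For the comparison of OE with WT, limma 3.58.1 in R 4.3.3 was fitted to log2(FPKM + 1) with an intercept and the genotype, with moderated variances that follow a trend with the mean level, two-sided, and Benjamini-Hochberg adjustment over the 17713 genes; the threshold was an adjusted p under 0.05. Log2 differences are on the log2(FPKM + 1) scale, which understates changes of weakly expressed genes. Of the genes past the threshold, those with a log2 difference of at least 1 in size were counted as changed 2-fold. Single values (means over a gene group, and TPS8) were compared by an exact two-sided permutation test over all 252 assignments of the 10 libraries, whose smallest p is 0.00794. In data simulated with 5 libraries per group over the 17713 genes, the fit recovered 91% of 200 genes changed 2-fold, 57% of those changed 1.5-fold and 0.5% of those changed 1.25-fold, with 4, 4 and 0 false calls, and 0 calls with no change. The simulated genes varied independently of each other, with normal noise and no differences shared by the genes of a library. The real genes varied together in part, so these counts give no error rate for the real data.

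Before the data were examined, 19 gene lists with 366 members were fixed from textbook knowledge, together with the tests and the rule for named genes. Lists with at least 5 tested members (17 lists) were tested by limma's camera with the preset correlation of 0.01, and beside it with an estimated correlation and by fry, in its directional and its mixed form. While camera compares a list with the other genes, fry asks only whether the members of the list changed. The rule named TPS8 and each trehalose gene past the threshold. It also named the 10 nuclear genes with the largest rise and the 10 with the largest fall among those past the threshold, with a mean of at least 5 FPKM in the higher group and no overlap between the groups. Per list it named up to 4 members with the smallest adjusted p past the threshold, or else the most abundant member. Genes outside the rule were named after their values were seen.

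Chosen after the data were examined were the enrichment of 359 annotation terms with 15 to 600 tested genes (hypergeometric test against 12054 annotated nuclear genes that were tested), the gene groups made from these terms and from product names, the within-group principal component as a covariate, the removal of trends with transcript length and GC content by a loess curve per library (span 0.5), and the omission of the 3 libraries with the most plastid RNA. Other settings fixed before the data were examined were pseudocounts of 0.1 and 0.5, no filter and a filter at 5 FPKM, quantile normalization, median-ratio scaling, a fit without the trend, sample weights, the replicate number as a block, omission of organelle genes, and omission of each library in turn. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.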

Results

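Transcripts of Arabidopsis thaliana shoots were measured by RNA-seq in 10 libraries. Of these, 5 came from wild-type plants of the accession Col-0 (WT) and 5 from a transgenic line that carries BnaC02.TPS8, a trehalose-6-phosphate synthase gene of oilseed rape (Brassica napus), behind the constitutive viral 35S promoter (OE). The values are FPKM (fragments per kilobase of transcript, scaled to the total of each library) for 32824 genes. They sum to between 918877 and 996313 per library. From the value that a single fragment gives to weakly expressed genes, the libraries were estimated to hold 1.83e+07 to 2.32e+07 fragments, for an assumed fragment length of 200 nt, so that the shallowest had 0.79 times the depth of the deepest. The series description calls the line O2 and the sample titles OE-11, so which line was sampled is unclear. The labels do not say whether the 5 samples of a group came from separate growth containers, so the p-values measure the spread between these samples only. According to the series description, the comparison of OE with WT served to find the pathways under the control of TPS8 in plants supplied with enough nitrogen.

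Transcripts of cytosolic ribosomal proteins, the protein parts of the ribosomes that translate nuclear mRNAs, rose together in OE shoots, and transcripts of 4 Arabidopsis genes of the trehalose phosphate synthase family fell. Among 192 tested genes annotated to cytosolic ribosomes, 166 rose and none fell, with a median ratio of OE to WT of 1.35 (log2 0.43). The Arabidopsis gene TPS8 (AT1G70290) fell from 83.7 ± 12.5 FPKM in WT to 41.9 ± 10.3 FPKM in OE (SD, n = 5). Across all 17713 tested genes, 512 passed the threshold of limma with Benjamini-Hochberg adjustment, of which 419 were higher and 93 lower in OE. Most of these changes were small: the median ratio was 1.34 among the higher genes and 0.752 among the lower ones, and 10 genes changed at least 2-fold. The groups did not overlap in 5.83% of all tested genes, where chance gives 0.794%. An unadjusted p under 0.05 was reached by 2682 of the 17713 tested genes, which is the background for such counts in the gene lists below.

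**Figure D1:**
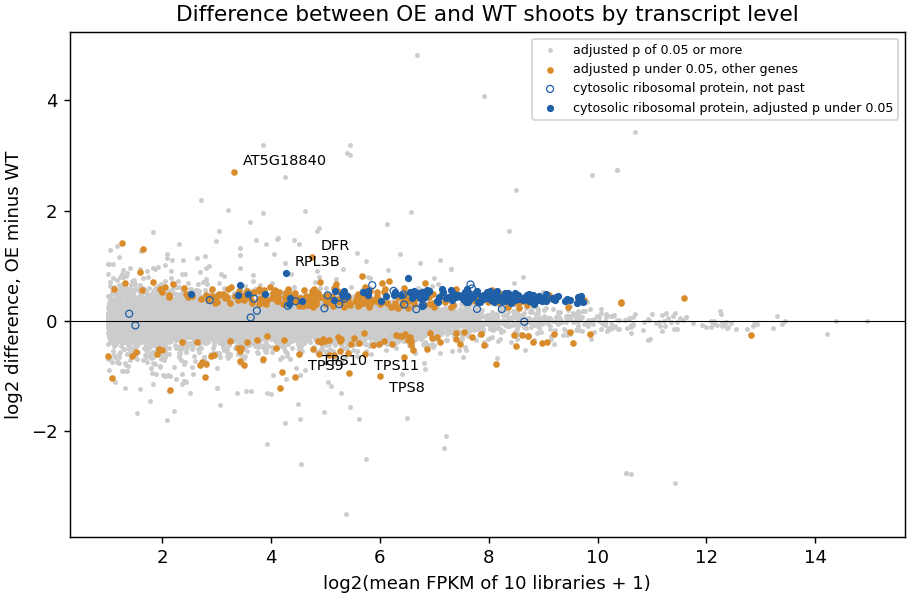
Each point is a gene. The horizontal axis gives the log2 of its mean FPKM over the 10 libraries plus 1, and the vertical axis the log2 difference between OE and WT; the 192 cytosolic ribosomal proteins are in blue, filled where they passed the threshold. The 166 filled blue points lie above 0, at log2 differences from 0.27 to 0.87, while TPS8 lies among the largest falls.

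The count of 512 leaned on several libraries. It was 291 (258 higher, 33 lower) without WT replicate 2, 277 (246 higher, 31 lower) without WT replicate 5, 207 (182 higher, 25 lower) without OE replicate 2 and 273 (231 higher, 42 lower) without OE replicate 4, and the lower genes numbered 57 without WT replicate 3 and 50 without OE replicate 5. Genes changed at least 2-fold numbered 6 without WT replicate 3 and 6 without OE replicate 5. With the 3 libraries of highest plastid RNA left out (WT replicates 2 and 4 and OE replicate 4), limma passed 0 genes, 1845 genes had an unadjusted p under 0.05, and the median log2 difference of the ribosomal proteins was 0.45. Among all 50 ways of leaving out 2 WT libraries and 1 OE library, the median count was 2 genes.

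Cytosolic ribosomal proteins were higher in each OE library than in any WT library when averaged over the 192 genes. The mean of log2(FPKM + 1) was 7.14 ± 0.11 in WT and 7.57 ± 0.07 in OE (SD, n = 5), a difference of 0.42 (SE 0.06; exact permutation p = 0.00794, two-sided, the smallest that 5 against 5 libraries can give). Of the 166 that rose, 165 had no overlap between the groups. RPL3B (AT1G61580), a copy of the large-subunit protein L3, had the smallest adjusted p of all genes and rose from 12.6 ± 0.808 to 23.9 ± 1.37 FPKM (log2 0.87, SE 0.07; limma adjusted p = 6.2e-04). AT2G37600, of the L36e family, rose from 67.1 ± 7.52 to 114 ± 5.96 FPKM (log2 0.77, SE 0.08; limma adjusted p = 0.0077). These genes were grouped after their values were seen, by the annotation terms of the TAIR10.1 reference. The terms also place in the group at least 4 proteins of mitochondrial or plastid ribosomes, MRPL11, NFD3, AT3G49080 and EMB3136, none of which passed (log2 0.21, 0.35, 0.18 and -0.02). The camera p of the group with an estimated correlation between members was 0.00932; this p and the exact permutation p do not count the choice of the group. Without OE replicate 2, 99 of them passed. Ribosomal proteins have near-identical copies, between which fragments can be split, so that the value of a single copy is less certain than that of the group.

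The annotation terms most enriched among the higher genes were those of the ribosome. Of 372 annotated higher genes, 201 carried the term for structural constituents of the ribosome, where 9.91 were expected. The term for the cytosolic large subunit held 83 of its 99 tested genes among the higher ones, and the term for the small subunit 71 of 80. Genes of the nucleolus, the nuclear site where ribosomes are assembled, were also enriched, with 50 of 190. This term shares members with those of the ribosome: with ribosomal proteins left out, 31 genes of the nucleolus and of ribosome assembly rose. In all, 18 of 359 terms were enriched among the higher genes and 4 among the lower genes by the hypergeometric test with Benjamini-Hochberg adjustment. That test takes genes as independent: in camera with an estimated correlation, the lowest adjusted p over the terms for ribosomes was 0.741.

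Genes of the nucleolus and of ribosome assembly that encode no ribosomal protein numbered 218, of which 31 rose and none fell. Their mean of log2(FPKM + 1) differed by 0.21 between OE and WT (SE 0.05; exact permutation p = 0.00794), and the camera p with an estimated correlation was 0.0447, neither of which counts the choice of the group after its values were seen. NOP10 (AT2G20490), part of the particles that guide pseudouridylation of rRNA, rose from 53.1 ± 6.40 to 87.6 ± 7.57 FPKM (log2 0.72; limma adjusted p = 0.00776). FIB2 (AT4G25630), a fibrillarin that methylates rRNA, rose from 21.8 ± 5.98 to 35.6 ± 5.55 FPKM (log2 0.71; limma adjusted p = 0.0472). HDA3 (AT3G44750), a plant-specific histone deacetylase of the nucleolus, rose from 36.4 ± 5.31 to 63.9 ± 6.18 FPKM (log2 0.80; limma adjusted p = 0.00776). AT5G20160 and AT4G12600, both of the L7Ae family of RNA-binding proteins, rose by log2 0.69 and 0.68, and AT4G15770, annotated as an RNA-binding protein, by 0.66 (limma adjusted p = 0.00776, 0.0146 and 0.00776, n = 5). The count of 31 was 20 without OE replicate 1, 16 without OE replicate 2, 19 without OE replicate 4 and 19 without WT replicate 5. FIB2 lost its call when any library except WT replicate 1 was left out, with a highest limma adjusted p of 0.128. It also lost it with no filter, quantile normalization, median-ratio scaling, no trend, organelle genes left out or length and GC trends removed (limma adjusted p = 0.0507 to 0.0776).

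**Figure D2:**
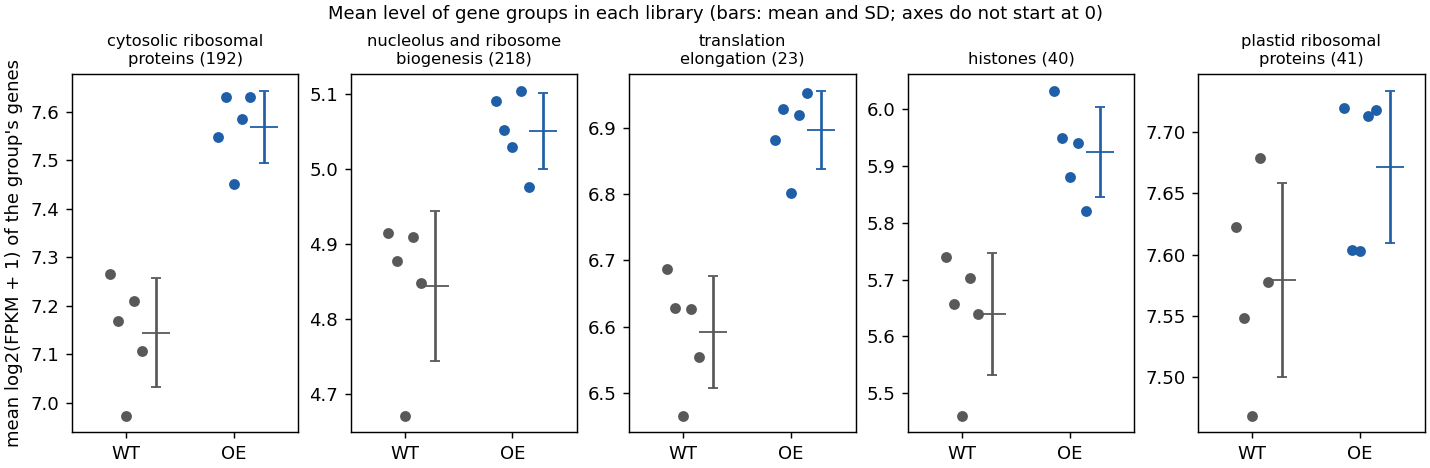
Each point is a library, placed at the mean of log2(FPKM + 1) over the genes of a group, whose number is in brackets; the bars give the mean and SD of the 5 libraries, and the vertical axes differ and do not start at 0. For the cytosolic ribosomal proteins the WT mean is 7.14 and the OE mean 7.57, without overlap, while for the plastid ribosomal proteins the libraries of both groups overlap.

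Transcripts for translation elongation and for histones also rose in part. In the elongation group, 14 of 23 genes rose. Of the 23, 10 are counted among the ribosomal proteins above, and all 10 of these rose. The mean over all 23 differed by 0.30 (SE 0.05, exact permutation p = 0.00794). It was not taken without the 10 shared genes, so it partly repeats the result for the ribosomal proteins. AT5G60390, one of the genes for elongation factor 1-alpha, which brings aminoacyl-tRNA to the ribosome, rose from 1229 ± 75.6 to 1530 ± 83.0 FPKM (log2 0.32; limma adjusted p = 0.0138). Of 40 histone genes, 12 rose, and the mean differed by 0.28 (SE 0.06; exact permutation p = 0.00794); HTA6 (AT5G59870), a histone H2A, rose from 131 ± 14.9 to 174 ± 10.4 FPKM (log2 0.41; limma adjusted p = 0.0201). Both groups and their examples were chosen after the values were seen. Without WT replicate 5, OE replicate 2 or OE replicate 4, 9, 5 and 9 elongation genes passed, and 5, 3 and 6 histone genes; without OE replicate 1, 6 histone genes passed. HTA6 missed the threshold in each of these 4 cases (highest limma adjusted p = 0.0645), and AT5G60390 without OE replicate 2 (0.0501). Of 41 ribosomal proteins of plastids that are encoded in the nucleus, 2 passed (1 with a smaller pseudocount, quantile normalization, median-ratio scaling, no trend, organelle genes left out or length and GC trends removed, and 1 without any of WT replicates 2, 3 and 5 or OE replicates 1, 2, 4 and 5), the difference of the means was 0.09 (SE 0.04), and the exact permutation p was 0.0635.

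Members of the trehalose phosphate synthase family fell in OE as far as they passed the test. TPS8 belongs to class II of the family, proteins similar to the synthase TPS1 whose own enzymatic activity is uncertain. In WT libraries 1 to 5 it stood at 96.0, 95.1, 84.5, 75.8 and 67.1 FPKM and in OE libraries 1 to 5 at 48.9, 53.5, 44.8, 32.3 and 30.2 FPKM, without overlap (ratio of the means 0.501, SE of the log2 difference 0.16; limma adjusted p = 0.00978; exact permutation p = 0.00794, n = 5). TPS11 (AT2G18700) fell from 62.9 ± 2.94 to 41.2 ± 4.99 FPKM (log2 -0.61, SE 0.08; limma adjusted p = 0.00776). TPS9 (AT1G23870) fell from 26.7 ± 4.43 to 17.2 ± 2.41 FPKM (log2 -0.61, SE 0.12; limma adjusted p = 0.0268), and TPS10 (AT1G60140) from 31.3 ± 5.47 to 21.4 ± 1.56 FPKM (log2 -0.51, SE 0.11; limma adjusted p = 0.0374). The remaining class II genes did not pass, with log2 differences of -0.40 for TPS5, -0.27 for TPS7 and -0.15 for TPS6 (limma adjusted p = 0.226, 0.321 and 0.534). TPS1, the main trehalose-6-phosphate synthase, stood at 14.0 ± 2.04 FPKM in WT and 13.3 ± 1.15 FPKM in OE (limma adjusted p = 0.831, n = 5). No row of the table measures the rapeseed transgene by itself, since every identifier is an Arabidopsis locus code. The values of TPS8 and its relatives may or may not include fragments of the transgene. The table thus cannot show whether the transgene was expressed. TPS9 lost its call without any 1 of 7 libraries (WT replicates 3 to 5, OE replicates 1, 2, 3 and 5; highest limma adjusted p = 0.0722) and TPS10 without any 1 of 9 (all but WT replicate 1; highest 0.0949), so that 2 of the 7 class II genes passed in most of these settings. TPS10 also lost its call with no filter, no trend or length and GC trends removed (limma adjusted p = 0.0585, 0.0521 and 0.0583).

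**Figure D3:**
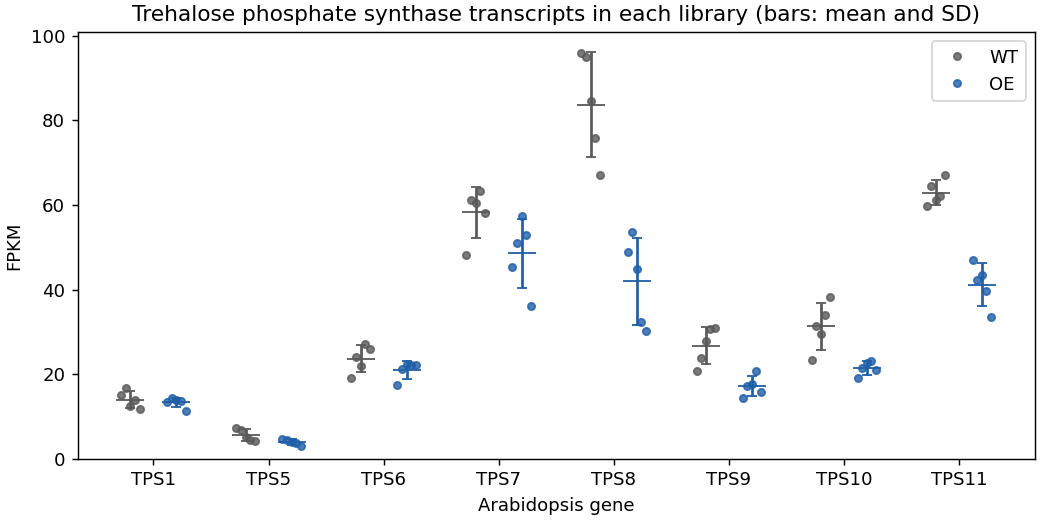
FPKM of 8 Arabidopsis genes of the trehalose phosphate synthase family in each WT and OE library (points), with the mean and SD of each group (bars). TPS8 lies between 67.1 and 96.0 FPKM in WT and between 30.2 and 53.5 FPKM in OE, while the groups overlap for TPS1.

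In the whole list of trehalose metabolism, fixed before the data were examined, 4 of 16 tested genes fell and none rose. Adjusted over the list alone, 5 fell and 3 rose: TPS5 joined the 4 that fell, and the rises were those of the trehalose-6-phosphate phosphatase genes TPPA, TPPB and TPPJ, whose products remove the phosphate from trehalose-6-phosphate. TPPA stood at 16.8 ± 3.02 FPKM in WT and 23.3 ± 4.48 in OE, TPPB at 1.18 ± 0.351 and 2.00 ± 0.384, and TPPJ at 3.34 ± 0.625 and 4.62 ± 0.794 (SD, n = 5), and none of these 3 passed over all genes (limma adjusted p = 0.173, 0.111 and 0.181). They were named after their values were seen. As a set the list did not pass in camera (adjusted p = 0.118), which looks for a shift in a single direction against the other genes. It passed in the mixed test of fry, which allows both directions (adjusted p = 2.4e-06). That test asks only whether members of the list changed, and 4 of them passed by themselves. It therefore does not set the list apart from other genes.

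Beyond the ribosome and the nucleolus, the largest rise under the rule for named genes was that of AT5G18840, a transporter of the major facilitator superfamily, from 1.58 ± 1.36 to 16.5 ± 9.41 FPKM (6.49-fold on the log2(FPKM + 1) scale, SE of the log2 difference 0.41; limma adjusted p = 0.00793). DFR (AT5G42800), dihydroflavonol 4-reductase of anthocyanin synthesis, rose from 16.6 ± 8.30 to 35.3 ± 6.17 FPKM (log2 1.15, SE 0.27; limma adjusted p = 0.0489). DFR lost its call when any library except WT replicates 1 and 2 was left out, with a highest limma adjusted p of 0.131. The call was also lost with no filter, median-ratio scaling, no trend, sample weights, organelle genes left out or length and GC trends removed (limma adjusted p of at least 0.0506). Another 2 genes rose at least 2-fold from lower levels, NUDT24 (AT5G19470), a nudix hydrolase, with 0.875 ± 0.807 FPKM in WT and 3.39 ± 0.565 in OE, and AT1G09003, a long non-coding RNA, by log2 1.41 from 0.379 ± 0.846 FPKM. Both fall outside the rule and were named after their values were seen. The WT values of AT1G09003 differed only through replicate 1, since its log2 difference was the same, 1.33, without any 1 of WT replicates 2 to 5. Its WT mean lay under the pseudocount of 1, so the size of its rise depends on that setting. AT1G09003 lost its call without any 1 of 9 libraries (all but WT replicate 1, highest limma adjusted p = 0.107). It also lost it with no filter, no trend or length and GC trends removed (limma adjusted p = 0.0704, 0.0519 and 0.0797).

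The largest falls under the same rule included several genes without a known function. AT3G43850 fell from 5.25 ± 1.82 to 1.54 ± 0.485 FPKM (log2 -1.26), AT4G33467 from 24.0 ± 6.49 to 9.76 ± 3.13 (log2 -1.23) and AT2G25200, of a family with the domain DUF868, from 27.9 ± 2.42 to 13.4 ± 3.57 (log2 -1.03), with limma adjusted p = 0.0108, 0.0120 and 0.00793. AT1G05753, a long non-coding RNA, fell by 1.02 on the log2 scale, from 8.21 ± 2.01 FPKM. AT1G67105, a non-coding RNA with less than the rule's minimum, fell from 1.85 ± 0.686 to 0.365 ± 0.124 FPKM and was named after its values were seen. AGP16 (AT2G46330), an arabinogalactan protein of the cell surface, was the most abundant of them and fell from 353 ± 37.1 to 206 ± 39.0 FPKM (log2 -0.79; limma adjusted p = 0.00793). NAC3 (AT3G15500), a transcription factor of the NAC family, fell from 7.19 to 3.78 FPKM (log2 -0.81, SE 0.15; limma adjusted p = 0.0173). The peroxidase gene AT2G37130, the acyl-transferase gene AT2G39980 and AT3G07350, of the DUF506 family, fell by 0.92, 0.80 and 0.81 on the log2 scale (limma adjusted p = 0.0376, 0.0103 and 0.0157). Left-out libraries ended 3 of these calls: that of AT1G05753 in 7 cases (all but WT replicate 5 and OE replicates 2 and 3; highest limma adjusted p = 0.0919), that of AT2G37130 in 7 (all but WT replicate 1 and OE replicates 1 and 3; highest 0.106) and that of NAC3 in 3 (WT replicate 5, OE replicates 2 and 4; highest 0.0567). With no filter AT1G05753 and AT2G37130 missed the threshold too (limma adjusted p = 0.0659 and 0.0667). AT2G37130 also did so with no trend or sample weights (limma adjusted p = 0.0509 and 0.0660).

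Genes in the list photosynthetic light reactions, which capture light and move electrons in the thylakoid membrane, lay slightly lower in OE as a set. Of 45 tested members 37 were below 0, with a median log2 difference of -0.06, and camera gave an adjusted p of 0.00222 with its preset correlation. With an estimated correlation that adjusted p was 0.888, and the exact permutation p of the mean over the list was 0.151. None of the 45 passed limma by itself, and 9 had an unadjusted p under 0.05. LHCB1.3 (AT1G29930), a chlorophyll-binding antenna protein, stood at 31519 ± 1931 FPKM in WT and 31513 ± 2836 in OE (n = 5). In the list starch and sucrose metabolism and sugar transport, 24 of 31 members were below 0, with a median of -0.08 (camera adjusted p = 0.0124 preset; adjusted p = 0.888 with an estimated correlation). None of these 31 passed limma, 8 had an unadjusted p under 0.05, and ADG1 (AT5G48300), the small subunit of the enzyme that makes ADP-glucose for starch, had 200 ± 10.1 and 198 ± 14.7 FPKM. Both lists missed the threshold without WT replicate 3 (camera adjusted p = 0.212 and 0.105) and without OE replicate 4 (0.130 and 0.0512), the light reactions also with quantile normalization (0.166), and starch and sucrose also with length and GC trends removed (0.0912).

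Flavonoid genes passed in both directions. In the list of phenylpropanoid, flavonoid and anthocyanin synthesis DFR rose and MYBL2 (AT1G71030), a repressor of anthocyanin synthesis, fell from 39.1 ± 3.68 to 25.4 ± 4.88 FPKM (log2 -0.62, SE 0.12; limma adjusted p = 0.0201), while the other 15 tested members did not pass. Adjusted over the list alone, CHS, the chalcone synthase that opens the flavonoid pathway, rose too, from 34.7 to 70.4 FPKM (limma adjusted p = 0.0557 over all genes); it was named after its values were seen. The list as a set did not pass (camera adjusted p = 0.219). MYBL2 missed the threshold without WT replicate 5, OE replicate 2 or OE replicate 4 (limma adjusted p = 0.0533, 0.0631 and 0.0564).

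RBCS1B (AT5G38430), a small subunit of Rubisco, was the 1 member of the 20 in the Calvin-Benson cycle that passed, from 2646 ± 312 to 3521 ± 163 FPKM (log2 0.42, SE 0.08; limma adjusted p = 0.0148). Its near-identical copies can share fragments with it, so this value is uncertain, and the call was lost without OE replicate 2 (limma adjusted p = 0.0520) and with quantile normalization (0.114). Adjusted over the list alone RBCS2B passed too, at 4589 FPKM in WT and 5193 in OE. In fatty acid and lipid synthesis, KASIII (AT1G62640), which starts fatty acid chains in the plastid, rose from 22.5 ± 1.54 to 27.7 ± 1.08 FPKM (log2 0.29, SE 0.06; limma adjusted p = 0.0299) as the 1 of 23 members past the threshold. KASIII lost its call without any 1 of 8 libraries (all but WT replicate 1 and OE replicate 5; highest limma adjusted p = 0.0942). Adjusted over the list alone, ACP4 and MCAT rose and PDAT1 fell as well, and these were named after their values were seen. The sets for the Calvin-Benson cycle and for fatty acids did not pass in camera (adjusted p = 0.616 and 0.406). The fatty acid list passed in the mixed test of fry (adjusted p = 9.4e-04), which does not compare it with other genes.

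Nitrogen genes did not pass limma over all genes, although the plants were grown to test TPS8 at sufficient nitrogen. Of 31 tested genes for uptake and assimilation of nitrate and ammonium, 10 had an unadjusted p under 0.05, as did 2682 of all 17713 tested genes. The camera adjusted p was 0.492, while the mixed test of fry, which allows both directions, gave an adjusted p of 9.4e-04. Since fry does not compare the list with other genes, that value does not set the list apart. GLN2 (AT5G35630), the plastid glutamine synthetase, stood at 1135 ± 17.5 FPKM in WT and 1125 ± 81.5 in OE (n = 5). Adjusted over the list alone, G6PD3 was higher (4.12 against 5.70 FPKM) and NLP7, a regulator of the nitrate response, lower (18.9 against 15.2 FPKM); both were named after their values were seen.

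In the other lists no member passed limma, over all genes or adjusted over the list alone. All 8 tested genes of the circadian clock were below 0, with a median log2 difference of -0.15 (camera adjusted p = 0.0567), and LUX, of the evening complex, stood at 67.9 ± 8.69 FPKM in WT and 58.7 ± 4.45 in OE; 1 of the 8 had an unadjusted p under 0.05. Of 17 sugar starvation markers of the kinase SnRK1, 13 were below 0 (median -0.18; camera adjusted p = 0.118) and 2 had an unadjusted p under 0.05, while SEN5 stood at 2443 ± 731 and 2348 ± 241 FPKM. The jasmonate and wounding list had a median of -0.20 over 12 genes (camera adjusted p = 0.0900; 3 at an unadjusted p under 0.05), with LOX2, a lipoxygenase of jasmonate synthesis, at 124 ± 35.8 and 104 ± 27.2 FPKM. The 12 cell cycle genes had a median of 0.13 (camera adjusted p = 0.219; 0 at an unadjusted p under 0.05), with the cytokinesis syntaxin KNOLLE at 49.1 ± 8.10 and 53.9 ± 3.81 FPKM.

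Chlorophyll synthesis (17 genes; PORB 1626 ± 168 and 1540 ± 136 FPKM) and glucosinolate synthesis (16 genes; MAM1 171 ± 36.7 and 167 ± 35.4 FPKM) did not pass as sets, at camera adjusted p = 0.616 and 0.955, and 1 and 0 of their genes had an unadjusted p under 0.05 in limma. The same held for salicylate and pathogen defence (10 genes; WRKY70 47.3 ± 27.0 and 40.4 ± 23.1 FPKM) and for abscisate, cold and dehydration (13 genes; KIN2 511 ± 85.0 and 511 ± 63.4 FPKM), both at camera adjusted p = 0.492, with 0 and 2 genes at an unadjusted p under 0.05. Phosphate starvation (6 genes; SQD1 47.0 ± 4.11 and 54.2 ± 3.80 FPKM) and iron status (8 genes; FER1 283 ± 88.2 and 288 ± 38.2 FPKM) had camera adjusted p = 0.616 and 0.853, with 1 and 2 genes at an unadjusted p under 0.05. Heat shock and root markers had 2 and 3 tested genes, too few for a set test, and 0 genes at an unadjusted p under 0.05 in limma. HSP18.2, a small heat shock protein, stood at 2.86 ± 1.01 and 3.06 ± 0.618 FPKM, and the root marker BGLU23 at 126 ± 23.4 in WT and 122 ± 29.3 in OE (SD, n = 5).

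Among the tested genes were 63 of the plastid and mitochondrial genomes, and none of them passed limma, with 1 at an unadjusted p under 0.05. The share of plastid transcripts in the summed FPKM varied within both groups, from 0.552% to 4.28% in WT and from 0.442% to 2.90% in OE. In a principal component analysis of the tested genes, the first component held 19.5% of the variance and did not separate the genotypes (exact permutation p = 0.579).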

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

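All values here were flagged because 1 library lay far from the other 4 of its group, by Dixon's criterion for 5 samples. In 116 groups of values checked, 10 were flagged, where chance flags about 1 in 20. Of these, 5 came from a single library, WT replicate 3: in WT, its mitochondrial transcripts made up 0.0170% of the summed FPKM (next 0.00528%), below OE replicates 2 to 5, which held 0.0182% to 0.0454%, and its nuclear rRNA genes 12978 FPKM (next 6375). Its gene AT4G12600 stood at 63.6 FPKM (next 87.9), its mean log2(FPKM + 1) of nucleolus and ribosome biogenesis genes at 4.67 (next 4.85), and that of photorespiration genes at 6.67 (next 6.78). Without WT replicate 3, 153 cytosolic ribosomal proteins rose in place of 166, and their median log2 difference was 0.38 in place of 0.43, the lowest for any single library left out.

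In WT, AT5G18840 had 3.94 FPKM in replicate 5, and the next highest library had 1.58. In OE, AT2G37600 had 125 FPKM in replicate 5 (next 114), AT3G43850 had 2.38 FPKM in replicate 2 (the other 4 lower), and the photorespiration genes had a mean log2(FPKM + 1) of 6.87 in replicate 5 (next 6.77). The mean mitochondrial share was 0.00693% in WT and 0.0243% in OE (exact permutation p = 0.0556, two-sided; Benjamini-Hochberg adjusted p = 0.278 over 5 library measures, a test chosen after the values were seen), with OE replicate 1 at 0.00327%, the lowest of all 10 libraries. Nuclear rRNA genes reached 18759 FPKM in OE replicate 4, against 8639 in the next OE library.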

How the results depend on the processing

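The settings with the within-group component, without trends of length and GC content, and without 3 libraries were chosen after the data were seen. None of the 512 genes, where still tested, had the opposite sign in any of 23 settings of the gene test. The sign could not change with another filter, without the trend, with the replicate block or with the within-group component, which leave the differences as they are. The settings with libraries left out reuse most of the libraries by which the genes were chosen, so a constant sign says little there. Of 26 named genes past the threshold, 16 passed in all 20 planned settings, and none of 15 others came to pass; TPS8 kept log2 differences between -1.10 and -0.90 when single libraries were left out. Sample weights gave -0.95; the permutation test of TPS8 was not run with sample weights, nor without the trend or with another filter, which leave its values as they are. Leaving out single libraries gave 207 to 536 genes, 182 to 431 higher, 25 to 105 lower, 6 to 14 at 2-fold, 99 to 168 ribosomal proteins, 16 to 34 nucleolus and ribosome biogenesis genes and 0 to 6 lists. Lower genes numbered 156 with quantile normalization, 141 with median-ratio scaling and 55 without the trend. The gene lists past the threshold numbered 1 with quantile normalization, 1 without the length and GC trends, and 0 with an estimated correlation and in the directional test of fry; its mixed test passed 3 lists, those of trehalose, of nitrate and ammonium, and of fatty acids (adjusted p = 2.4e-06, 9.4e-04 and 9.4e-04). The within-group component as a covariate gave 848 genes, 223 lower, 16 at 2-fold, 53 nucleolus and ribosome biogenesis genes and 5 lists. That component was computed from the deviations of these same libraries from their group means. It leaves the differences as they are and takes up the largest part of the spread, so its p-values are likely too small and its higher counts are no support. With the 3 libraries of most plastid RNA left out, limma passed 0 genes (0 higher, 0 lower, 0 at 2-fold, 0 ribosomal proteins, 0 nucleolus genes, with 1845 at an unadjusted p under 0.05) and camera 4 lists. With 7 libraries left, 10 of all 50 such omissions passed 0 genes. Over all 50, the ribosomal protein median ranged from log2 0.34 to 0.52. The cause of the other shifts was not tested.

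Same-numbered libraries did not all deviate together: their deviations from the group means correlated at 0.20, -0.04, -0.09, 0.07 and 0.18, and 2 of 5 WT and 2 of 5 OE libraries correlated best with their own number, although the leading within-group component followed the order of the numbers. With the replicate number as a block, 781 genes passed, 189 lower, 17 at 2-fold, with 54 nucleolus and ribosome biogenesis genes and 4 lists. No setting varied the depth.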

Other observations

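Photorespiration recycles the product of Rubisco's reaction with oxygen through peroxisomes, and some of its genes fell in OE. HPR, hydroxypyruvate reductase, stood at 460 FPKM in WT and 379 in OE (log2 -0.28; limma adjusted p = 0.0230), AGT at 1013 and 854 (log2 -0.24) and GGT1 at 774 and 674 (log2 -0.20), and these 3 of 26 photorespiration genes passed. At an unadjusted p under 0.05 in limma, 4 of the 26 were higher and 4 lower. The term for peroxisomes, which includes these 3 genes, had 7 of 112 genes among the lower ones, where 0.557 were expected. The others were TGG2 (log2 -0.47), the catalase CAT1 (log2 -0.37), AT4G02340 (log2 -0.35) and the malate dehydrogenase PMDH2 (log2 -0.25). NDPK1 of the same term rose (log2 0.33, limma adjusted p = 0.0423). NDPK1 lost its call when any library except WT replicate 1 was left out, and with no filter, median-ratio scaling, no trend or length and GC trends removed (highest limma adjusted p = 0.277). As whole groups, photorespiration and peroxisome genes gave no low p for the mean level (exact permutation p = 0.556 and 0.127, n = 5), and the median of the 26 photorespiration genes was 0.06, opposite to the 3 that passed. Without WT replicate 2, WT replicate 5 or OE replicate 2, limma passed 0 peroxisome genes (20 at an unadjusted p under 0.05 with all libraries), and 3 without WT replicate 3, WT replicate 4, OE replicate 1 or OE replicate 4, and 4 without OE replicate 3 or OE replicate 5. Photorespiration genes numbered 0 without WT replicates 2, 4 or 5 or OE replicate 2, and 1 without WT replicate 3 or OE replicates 1, 3 or 4. Other settings also moved the counts of 7 and 3: to 2 and 0 without the trend, 3 and 1 with no filter, and 4 and 1 with median-ratio scaling or with length and GC trends removed. They were 0 and 0 with 3 libraries left out, while the within-group component as a covariate gave 11 and 4, with p-values that are likely too small. Of 18 tested genes of the term for ATP-dependent peptidases, 3 fell: VAR2 and FTSH1, proteases of the thylakoid, and CLPC1, a chaperone subunit of the Clp protease, by 0.25, 0.25 and 0.28 on the log2 scale (limma adjusted p = 0.0153, 0.0226 and 0.0189). Of these 3, 1 passed without WT replicate 2 or WT replicate 5, 2 without OE replicate 4, and 0 without OE replicate 2 or without the trend, and FTSH1 also missed the threshold with length and GC trends removed (6 of the 18 had an unadjusted p under 0.05 in limma with all libraries). All these groups were chosen after the values were seen.

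The tests below were chosen after the result was seen, except the splits for the numbers of genes and lists, the principal component in the test of TPS8 and the correlation with the plastid share. The split test on annotation terms was set up after the rise of the ribosomal proteins was known and before any other split was measured for it.

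Cytosolic ribosomal protein transcripts were higher in OE by a median of log2 0.43. Their short length or GC content explains little of the rise: 192 other genes matched in length, GC content and level had a median of log2 0.0465. The 95% bootstrap range was 0.03 to 0.07, from draws of genes and not of libraries. Of the 192 matched genes, 15 passed as higher, against 419 of all 17713 tested genes. The 419 include ribosomal proteins and genes of the nucleolus and ribosome biogenesis, which were kept out of the matched genes. Outside these groups 222 genes rose. Calls were thus more frequent among the matched genes than among other genes, although their median difference was small. With length and GC trends removed, 143 ribosomal proteins passed and their median was 0.37, so a part of the difference may be technical. Scaling and organelle RNA are argued against as well, since the median of the group stayed at 0.34 or more with organelle genes left out, median-ratio scaling and quantile normalization. A larger share of dividing tissue cannot be told apart here: the cell cycle list differed by 0.11 (SE 0.11), against 0.42 for the ribosomal proteins, but 10 of its 12 genes were above 0, and the histone genes, transcribed in S phase, differed by 0.28 (SE 0.06). An effect of the transgene on ribosome production, a difference in growth between the plants and an effect of the insertion in this line stay open and were not tested.

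Chance assignment of libraries was tested on 100 of the 126 splits of the 10 libraries into groups of 5. Only 1 of the 100, the real one, gave as many as 512 genes, and the highest other gave 135. For ribosomal proteins that rose, 1 of 100 gave 166 and the highest other 0, which decides nothing, since the group was chosen under the real labels and 86 of the other splits passed no gene at all. With the annotation term of largest median chosen anew in each split, 1 of 100 gave a median as far from 0 as the real log2 0.439 of the cytosolic large subunit, and the highest other gave 0.346. For gene lists chance is not excluded: 90 of 100 splits gave 2 lists or more, and the highest gave 11; leaving out single libraries gave 6 without WT replicate 1, 5 without WT replicate 2, OE replicate 1 or OE replicate 5, and 0 without WT replicate 3 or OE replicate 4. The split with 135 genes set WT replicates 1 to 3 and OE replicates 1 and 2 against the rest. It follows the order of the replicate numbers, and its gene count points to a structure of the samples that the genotype does not explain. Its 11 lists do not, since splits outside that order gave 11 too. An example is WT replicates 1 and 5 with OE replicates 3 to 5, which passed 0 genes.

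Arabidopsis TPS8 fell in the line meant to overexpress its rapeseed counterpart. With the first principal component as a covariate the log2 difference was -0.91 (SE 0.09, limma adjusted p = 0.00521). That component did not separate the genotypes (exact permutation p = 0.579). A component that does not separate the genotypes can account for little of a difference between them, and the fit left -0.91. These values argue against the leading difference between libraries as the source of the fall of TPS8. This holds for the first component only, and not for other differences between libraries. Whether TPS8 to TPS11 may have fallen as part of a general fall of sugar starvation transcripts cannot be told apart here: the 17 markers had a median of -0.18, against -0.61 for the 4 genes, and ranged from -0.71 to 0.79. Feedback of the transgene on the endogenous genes remains a hypothesis that was not tested.

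Within the groups, libraries differed along a component that held 22.5% of the within-group variance. It rose with the replicate number in both groups (mean Spearman's rho = 0.95, exact permutation p = 0.00125, Benjamini-Hochberg adjusted p = 0.0025 over 2 relations); what the numbers stand for is not given in the sources used here. It may reflect the time of harvest: the 8 tested clock genes had a mean absolute correlation of 0.53 with it (from -0.87 for CCA1 to 0.93 for TOC1), at percentile 74.2 of 10000 random lists of the same level, which does not decide the question, and the labels give no harvest time. The plastid share is open too, with Pearson's r = 0.36 (permutation p = 0.295) and Spearman's rho = 0.33 (permutation p = 0.348) over 10 libraries, and r = 0.40 without the 2 libraries farthest from the median. Of 359 annotation terms, 36 passed in camera with its preset correlation, 27 falling and 9 rising along the component. The smallest adjusted p were those of oxygen binding and monooxygenase activity (camera adjusted p = 8.7e-05 and 1.7e-04), which both fell. Chlorophyll binding fell too (median r = -0.43), while vesicle transport rose (median r = 0.45). An estimated correlation was not used for these terms.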
